A study of Caenorhabditis elegans with 6 samples.

How the data were processed

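RNA was extracted from whole wild-type Caenorhabditis elegans hermaphrodites in 6 libraries, 3 from control animals and 3 from animals given 5 mM tryptophan from the last larval stage (L4) onward for 36 h at 20 °C. Libraries were made from total RNA with a TruSeq RNA kit, per the labels' protocols. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate cultures, so the p-values measure only the spread between these libraries.

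The authors deposited one table of FPKM values (fragments per kilobase of gene model and scaled to library size) per library, per the file headers. Bowtie 0.12.2 and StringTie are named as tools and WBcel235 as genome build, per the submitters' processing notes. The annotation release, filters, strandedness and any scaling between libraries are not given in the sources used here. The tables held 46589 gene identifiers, of which 45362 matched a gene of the WBcel235 annotation (Ensembl release 115) and 1227 did not. Coordinates come from that annotation and are 1-based. No count model was used, since the values are not counts.

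Depth was estimated from the low values. FPKM multiplied by transcript length, over 12481 genes with a single annotated transcript of at least 600 bp, fell on whole multiples of one step per library for 71.6% to 76.6% of low values, at a tolerance of 0.2 steps. The steps correspond to 14.8, 21.5 and 20.0 M (mega) counted units in control libraries 1 to 3 and 17.5, 20.7 and 25.1 M in tryptophan libraries 1 to 3. Whether a unit is a read or a read pair could not be told. Because the other low values were not near a whole multiple, no counts were rebuilt.

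Values were analysed as log2(FPKM + 1), and a log2 fold change on this scale understates the change of genes with low FPKM. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which kept 13511 genes, 12783 of them protein coding. Tryptophan was compared with control in limma 3.58.1 (R 4.3.3, statmod 1.5.0) by a linear model on group and eBayes with trend, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. An exact permutation test of 3 against 3 cannot go below p = 0.10 and was not used for single genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

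Gene groups were tested with limma's camera at a preset inter-gene correlation of 0.01, on 47 gene lists fixed before the data were examined (46 had at least 5 tested members) and on 116 gene classes that share the stem of their symbol (at least 10 tested members). A list of male somatic genes had 0 tested members, its highest FPKM being 1.65. The annotation gives the mitochondrial genome's genes other symbols than the list did, so that list was taken as the protein-coding genes of that chromosome. Members of each list were also adjusted over the list alone.

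The genes named were set by a rule fixed before the data were examined. Since 0 genes passed over all genes tested, it gave the 10 genes with the smallest p in each direction, 12 genes named whatever their values, up to 4 members of each list that passed, and up to 2 of each list that did not. For lists that passed as a set, members were named from those past the threshold over the list alone, or by smallest p where there were none. That extension, and the use of the rule's 12 largest changes in each direction for the comparison of libraries 2 and 3, with genes annotated as piRNA or ncRNA left out but small nucleolar RNAs kept, were made after the values were seen.

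The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median rescaling, quantile normalization, rescaling to TPM, a replicate block, robust eBayes, eBayes without trend, an absolute log2 fold change of at least 1, each library left out in turn, camera with an estimated correlation, and fry. Another 3 were added after seeing the data: libraries 2 and 3 of each group only, a stage score as covariate (mean log2 of the yolk genes minus mean log2 of the sperm genes), and limma's array quality weights.

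The tests were tested on simulated data in which the real residuals of the 13511 genes were rotated at random over the libraries in 20 draws, with changes added to a random subset of genes. For 3 against 3 libraries, 2%, 6%, 27% and 51% of genes changed by log2 1, 2, 3 and 4 were called, and calls among unchanged genes occurred in 3 of the 20 draws, with up to 3309 in one. For 2 against 2 libraries (2 and 3 of each group), 11%, 76%, 93% and 96% were called, and calls among unchanged genes occurred in 4 of the 20 draws, with up to 2941 in one. Without any change, camera at the preset correlation called a median of 15.5 lists (at most 19) for 3 against 3 libraries and 12 (at most 18) for 2 against 2. With an estimated correlation the median was 0 in both.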

Results

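Whole-animal mRNA levels were measured in young adult Caenorhabditis elegans hermaphrodites, a free-living nematode, after 36 h with or without 5 mM tryptophan, an essential amino acid. There were 3 control and 3 tryptophan libraries at an estimated 14.8 to 25.1 M (mega) counted units each, and 13511 genes were abundant enough to test. The single comparison asks which transcripts differ in abundance when tryptophan is fed.

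Genes of the xenobiotic response, above all the cyp-35 family of cytochrome P450 enzymes that oxidise foreign compounds, were higher with tryptophan. The list fixed for this response held 17 tested genes, of which 12 had a positive log2 fold change, 11 had every tryptophan library above every control library, and 9 rose when adjusted over the list alone (limma), against 0 over all genes tested. cyp-35A3 (K09D9.2, chromosome V, 4022609 to 4024482) stood at 4.01 ± 3.71 FPKM in control and 114.3 ± 40.3 FPKM in tryptophan animals (SD, n = 3 each), with control values of 0.172, 4.27 and 7.59 FPKM. cyp-35A4 (C49G7.8, chromosome V, 4031619 to 4033446) went from 1.46 ± 1.16 to 48.4 ± 21.8 FPKM, cyp-35A5 (K07C6.5, chromosome V, 3936326 to 3938597) from 1.63 ± 0.902 to 20.3 ± 2.88 FPKM, and cyp-35C1 (C06B3.3, chromosome V, 13896663 to 13898487) from 11.96 ± 7.62 FPKM to 128.1, 105.9 and 110.9 FPKM in the 3 tryptophan libraries. Their log2 fold changes were 4.88 (SE 0.76), 4.37 (SE 0.56), 3.08 (SE 0.45) and 3.41 (SE 0.59), with limma adjusted p of 0.00164, 0.00140, 0.00161 and 0.00202 over the list alone and 0.579, 0.372, 0.579 and 0.731 over all genes.

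The other members that rose over the list alone were cyp-35A1, cyp-35A2, cyp-35B1, cyp-35B2 and pgp-1, a drug efflux pump. Their log2 fold changes were 2.21, 2.95, 1.39, 2.27 and 1.47. All but pgp-1 of the members that rose are cyp-35 genes, and the 5 members with a negative log2 fold change include none of that family. The list mean and set test thus rest largely on the cyp-35 genes. As a set the list passed camera (adjusted p = 7.4e-13, median log2 fold change 1.39), with adjusted p = 0.667 with an estimated correlation. In control libraries 1 to 3 the mean of the list was 1.56, 2.41 and 2.57 on the log2 scale, and in tryptophan libraries 1 to 3 it was 3.82, 3.87 and 3.69. Among all 47 tested cytochrome P450 genes 9 rose when adjusted over the list alone, each of them a cyp-35 gene, and 0 over all genes (camera adjusted p = 6.0e-05, or 0.667 with an estimated correlation). All but cyp-35D1 of these 9 are also in the xenobiotic list. The count of 9 was 6 without tryptophan library 2 or 3 and 5 with a filter of 5 FPKM. The P450 mean was 1.94 in control library 1 and 3.10 in tryptophan library 1, which stand apart, against 2.38 to 2.87 in the other 4. In libraries 2 and 3 the median log2 fold change of the P450 list was 0.00, against 0.33 over all libraries, with 24 of 47 positive (adjusted p = 0.0379; adjusted p = 0.947 with an estimated correlation). Leaving out any 1 library left 8 or 9 members of the xenobiotic list past the threshold over the list alone, and a filter of 5 FPKM left 5. The cyp-35A genes are close paralogs, so how reads were divided among them is uncertain.

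**Figure D1:**
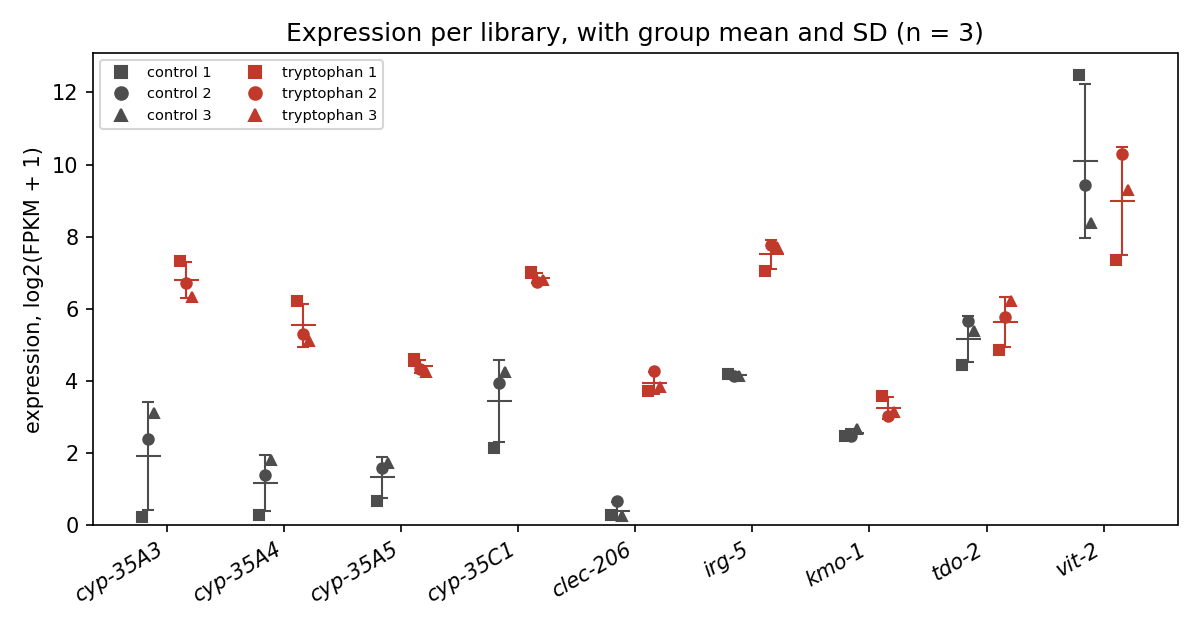
Expression of 9 genes in each library as log2(FPKM + 1) on the vertical axis, with genes along the horizontal axis. Points are libraries (grey control, red tryptophan, shape by replicate number), and bars give the group mean and SD (n = 3). The 4 cyp-35 genes, clec-206, irg-5 and kmo-1 have no overlap between groups, while the ranges of tdo-2 and vit-2 overlap.

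Some genes of innate immunity that respond to the p38 kinase pathway were also higher with tryptophan. Of 25 tested members of that list, 15 had a positive and 10 a negative log2 fold change, and 4 rose when adjusted over the list alone and 0 over all genes tested. irg-5 (F35E12.5, chromosome V, 13737010 to 13738474), an infection response gene, stood at 16.8 ± 0.241 FPKM in control and 185.7 ± 46.6 FPKM in tryptophan animals (SD, n = 3 each). Its log2 fold change was 3.35 (SE 0.37), with limma adjusted p = 7.0e-04 over the list alone and 0.188 over all genes. irg-4 (F08G5.6) went from 35.1 ± 23.7 to 285.1 ± 27.1 FPKM, C32H11.4 from 21.9 ± 9.05 to 92.5 ± 15.02 FPKM, and irg-6 (C32H11.1) from 0.755 ± 0.403 to 4.09 ± 1.17 FPKM, with limma adjusted p of 0.0126, 0.0126 and 0.0251 over the list alone. The list passed camera (adjusted p = 0.00262; adjusted p = 0.667 with an estimated correlation), with a median log2 fold change of 0.18. Without tryptophan library 3, 1 member passed over the list alone, and without control library 2, 2 members did. Without tryptophan library 2 the list did not pass camera (adjusted p = 0.0691).

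Among 94 tested C-type lectin genes, which encode carbohydrate-binding proteins, 1 rose when adjusted over the list alone and 0 over all genes, and the list did not pass camera (adjusted p = 0.0680). Without control library 1, 2 members passed over the list alone. The gene past it over all 6 libraries was clec-206 (F59A7.1, chromosome V, 2000418 to 2004329), at 0.334 ± 0.226 FPKM in control and 14.6 ± 3.36 FPKM in tryptophan animals (SD, n = 3 each). Its log2 fold change was 3.54 (SE 0.38), the smallest p of all genes tested, with limma adjusted p = 0.00235 over the list alone and 0.188 over all genes. Of 12 metal response genes, cdr-1 and cdr-4 rose when adjusted over the list alone (log2 fold change 2.76 and 1.64, limma adjusted p 0.0240 and 0.0373). That count was 0 over all genes tested, and 0 over the list alone without control library 3 or without tryptophan library 1 or 2, and 1 without tryptophan library 3. With a replicate block it was 0 over the list alone, and with quantile normalization or rescaling to TPM it was 1. The metal mean was 4.33 in tryptophan library 1, which stands apart, against 3.46 and 3.56 in tryptophan libraries 2 and 3 and 2.95 to 3.31 in the controls. The metal list passed camera (adjusted p = 0.0238; adjusted p = 0.667 with an estimated correlation) but not without control library 3 (0.0554) or tryptophan library 1 (0.210), without a filter (0.0639), with quantile normalization (0.0562) or in libraries 2 and 3 alone (0.470).

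Conjugating enzymes of detoxification had mostly positive values. Of 51 UDP-glucuronosyltransferase (ugt) genes 34, and of 39 glutathione S-transferase (gst) genes 36, had a positive log2 fold change, and 0 passed over all genes or when adjusted over the list alone. Over the list alone 2 ugt genes rose with rescaling to TPM, 1 without a filter and 6 with a stage score as covariate, a setting chosen after seeing the data. Both lists passed camera (adjusted p = 6.1e-06 for ugt and 1.3e-07 for gst; adjusted p = 0.667 with an estimated correlation for both). Values with the smallest p were a log2 fold change of 1.44 (SE 0.28) for ugt-67, 1.88 (SE 0.44) for ugt-16, 2.09 (SE 0.58) for gst-5 and 2.15 (SE 0.68) for gst-38. The gst mean was 5.18 in tryptophan library 1, against 3.32 to 3.97 in the controls and 3.85 and 3.89 in tryptophan libraries 2 and 3, so it moved with a library that stands apart, and the list did not pass in libraries 2 and 3 (adjusted p = 0.376). The ugt mean was 2.56 in control library 1, against 3.13 to 3.47 in the other 5. In libraries 2 and 3 the mean log2 fold change of ugt genes was 0.21, against 0.42 over all libraries, and the list passed (adjusted p = 0.00483; adjusted p = 0.902 with an estimated correlation), with 10 members higher and 3 lower when adjusted over the list alone and 4 higher over all genes. The oxidative stress list controlled by SKN-1 did not pass (adjusted p = 0.0650) but did in 6 of 18 alternatives. gst-4, a common reporter of it, stood at 107.6 ± 9.15 FPKM in control and 166.0 ± 87.5 FPKM in tryptophan animals. The gst-4 difference rests mostly on tryptophan library 1 (266.2 FPKM, against 104.4 and 127.5 FPKM in tryptophan libraries 2 and 3). Its log2 fold change was 0.50 over all libraries and 0.17 in libraries 2 and 3.

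Enzymes that break down tryptophan did not pass as a list or singly. The 10 tested genes of the kynurenine route had a median log2 fold change of 0.22 (camera adjusted p = 0.259), with 0 members past the threshold over all genes or when adjusted over the list alone. tdo-2, which opens the route, stood at 37.1 ± 14.7 FPKM in control and 51.9 ± 22.8 FPKM in tryptophan animals (SD, n = 3 each; log2 fold change 0.45, SE 0.52). kmo-1 had 4.85 ± 0.482 and 8.65 ± 2.08 FPKM, a log2 fold change of 0.70 (SE 0.39, limma adjusted p = 0.802). The groups did not overlap for kmo-1, as was so for 8.3% of all tested genes. The log2 fold changes of kynu-1 and haao-1 were -0.25 (SE 0.46) and 0.00 (SE 0.46). nkat-1 and tph-1, the latter encoding the first enzyme of serotonin synthesis, were below the expression filter at means of 0.840 and 0.195 FPKM in control and 0.807 and 0.349 FPKM in tryptophan animals. The serotonin, NAD synthesis, tyrosine and phenylalanine, and amino acid transport lists did not pass camera (adjusted p = 0.383, 0.325, 0.762 and 0.762). Their members with the smallest p were qdpr-1 (60.7 ± 20.4 FPKM in control and 29.9 ± 14.6 FPKM with tryptophan), nprt-1, gst-42 and skat-1, the last 3 with log2 fold changes of -1.08 (SE 0.65), 0.82 (SE 0.40) and -1.51 (SE 1.03). The values of nprt-1 and skat-1 rest on control library 1 (81.2 and 68.9 FPKM) and tryptophan library 1 (8.26 and 1.61 FPKM), with 27.7 to 33.9 FPKM for nprt-1 and 28.1 to 35.7 FPKM for skat-1 in the other 4, and in libraries 2 and 3 the log2 fold changes were -0.04 and 0.11. Those of kynu-1 and haao-1 were 0.17 and -0.32 there.

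Stress markers were not past the threshold. The heat shock list had adjusted p = 0.458, and hsp-16.2, a small heat shock protein gene, had 230.8, 700.0 and 346.8 FPKM in the controls and 1685, 312.2 and 734.9 FPKM with tryptophan. The lists of the endoplasmic reticulum and mitochondrial unfolded protein responses had adjusted p of 0.907 and 0.140, with log2 fold changes of 0.27 (SE 0.34) for hsp-4 and -0.82 (SE 0.78) for hsp-6. The hsp-6 value rests on tryptophan library 1 (47.7 FPKM, against 354.7 and 305.6 FPKM in tryptophan libraries 2 and 3), and in libraries 2 and 3 it was 0.33. The class 1 targets of the FOXO factor DAF-16 had adjusted p = 0.606, and the log2 fold change of sod-3 was 0.42 (SE 0.58). The hypoxia and hydrogen sulfide list (0.358), the intracellular pathogen list (0.715) and the starvation list (0.397) did not pass either.

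The other genes among the 10 smallest p in the higher direction were fbxo-11.2 (log2 fold change 2.86, SE 0.47) and stdh-2, of a steroid dehydrogenase family (2.82, SE 0.48), with limma adjusted p of 0.669 and 0.726. In the lower direction none of the 10 passed over all genes, with limma adjusted p from 0.579 to 0.802. They included fat-7, a fatty acid desaturase (78.4 ± 42.03 FPKM in control and 26.1 ± 3.09 FPKM with tryptophan), lips-15, a lipase-like gene (10.8 ± 0.637 and 2.91 ± 0.995 FPKM), and the lectin genes clec-47 (36.8 ± 11.7 and 9.52 ± 9.73 FPKM) and clec-48 (log2 fold change -1.06, SE 0.36). The log2 fold changes of srh-237, pinn-1, the histone H4 gene his-31 and F22H10.2 were -1.39, -1.35, -1.31 and -1.19. Values of his-31 were near the detection floor, at 4.03, 0.973 and 1.05 FPKM in the controls and 0.340, 0 and 0 FPKM with tryptophan. A pair of very short RNAs, Y37E3.24 and 21ur-6528, were listed at 0 in all 3 tryptophan libraries, with 7.92, 2.73 and 5.88 FPKM and 3.21, 2.21 and 4.76 FPKM in the controls. They span bases 2149987 to 2150003 and 15900986 to 15901006. A counted unit is a step of 46.49 to 67.43 FPKM times bp in the controls. On RNAs this short the control values therefore stand for very few counted units, near the detection floor.

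Germline, yolk and cuticle genes differed mainly between libraries and not between groups. Control library 1 and tryptophan library 1 lay at opposite ends of the first principal component (-140.7 and 117.5, 68.2% of the variance), with the other 4 libraries between them. On the second component (24.6% of the variance) both lay on the same side, at 55.3 and 68.7, against -45.0 to -9.1 in the other 4 libraries. The correlation of control library 1 with tryptophan library 1 across genes was 0.578, against 0.960 to 0.980 among the other 4 libraries. Yolk genes had a mean of 11.41 on the log2 scale in control library 1 and 5.81 in tryptophan library 1, against 7.47 and 6.66 in control libraries 2 and 3 and 8.77 and 7.65 in tryptophan libraries 2 and 3. Sperm genes ran the other way, at 2.40 in control library 1, 6.52 in tryptophan library 1 and 4.95 to 5.48 elsewhere. vit-2, which encodes a yolk protein, reached 5708 FPKM in control library 1 and 161.7 FPKM in tryptophan library 1.

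**Figure D2:**
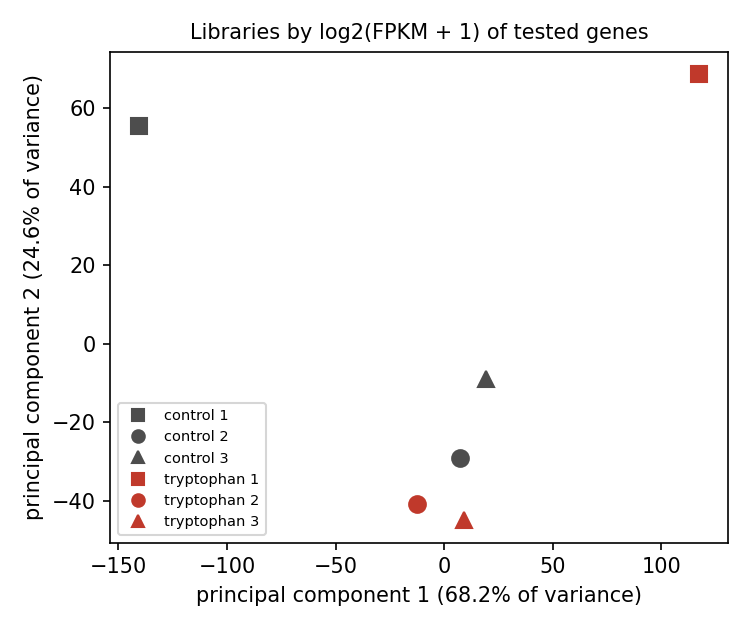
Position of the 6 libraries on the first 2 principal components of log2(FPKM + 1), with the share of variance on each axis (68.2% and 24.6%). Grey is control, red is tryptophan and the shape gives the replicate number; the libraries numbered 1 lie far from the other 4 and at opposite ends of the horizontal axis.

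The oocyte list (all 30 members negative, median log2 fold change -1.12, camera adjusted p = 1.7e-11) and the sperm list (83 of 87 positive, median 1.18, adjusted p = 9.1e-12) passed camera with 0 members past the threshold over all genes or when adjusted over the list alone, and both had adjusted p = 0.667 with an estimated correlation. The oocyte mean was 8.85 in control library 1 and 5.68 in tryptophan library 1, and 6.67 to 7.20 in the other 4. In libraries 2 and 3 alone the oocyte list did not pass (adjusted p = 0.486) and the sperm list turned direction (median -0.32, adjusted p = 2.4e-10; adjusted p = 0.538 with an estimated correlation). Cuticle collagens turned likewise, from a median of 0.78 over all libraries (adjusted p = 0.0465; adjusted p = 0.778 with an estimated correlation) to -0.61 in libraries 2 and 3 (adjusted p = 1.6e-29; adjusted p = 0.538 with an estimated correlation), where 66 of 129 collagens, for example col-104 and col-62 (log2 fold change -1.18 for both), fell when adjusted over the list alone and 0 over all genes. Without control library 1 the sperm list did not pass (adjusted p = 0.111) and the collagen list passed in the lower direction (1.6e-15), and without tryptophan library 1 the collagen list did not pass (0.810). The collagen list also did not pass without a filter (0.608), with rescaling to TPM (0.288) or with a replicate block (0.0840). The antimicrobial peptide and lysozyme list went from a median of 0.43 (adjusted p = 1.6e-04; adjusted p = 0.715 with an estimated correlation) to -0.43 (adjusted p = 6.8e-08; adjusted p = 0.809 with an estimated correlation), and did not pass without tryptophan library 1 (0.0822). Yolk genes went from a median log2 fold change of -1.13 (adjusted p = 0.0909), with 0 of 6 members positive, to a mean of 1.14 with 6 of 6 positive (adjusted p = 9.6e-05; adjusted p = 0.809 with an estimated correlation).

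**Figure D3:**
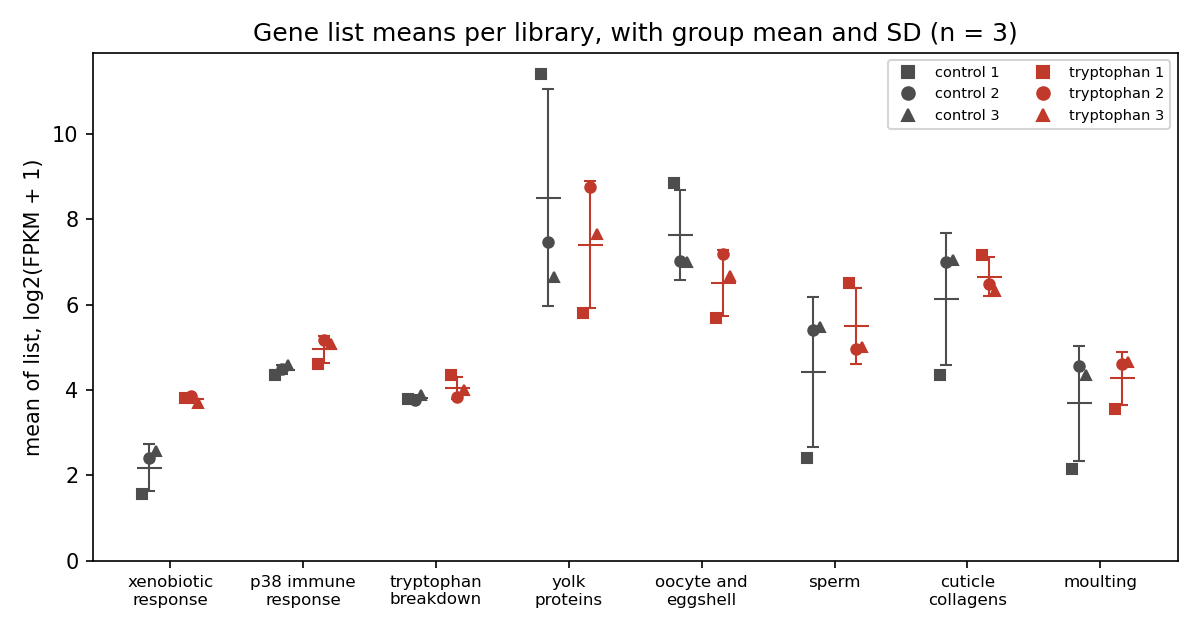
Mean log2(FPKM + 1) of 8 gene lists in each library on the vertical axis, with the lists along the horizontal axis; points are libraries (grey control, red tryptophan, shape by replicate number) and bars are group mean and SD (n = 3). The xenobiotic list lies at 1.56 to 2.57 in controls and 3.69 to 3.87 with tryptophan, while yolk, oocyte, sperm and collagen lists are spread by the libraries numbered 1.

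With those libraries left out, a choice made after seeing the data, limma called 68 genes, 34 higher and 34 lower with tryptophan. The median residual SD was 0.20 on the log2 scale in these 4 libraries and 0.64 in all 6. Of the calls 6 higher and 7 lower ones were annotated as piRNA or ncRNA, such as F35G2.12 (log2 fold change 3.15) and Y37E3.24 (-2.34), and these were left out of the largest changes named here. Those annotated as piRNA, and Y37E3.24, had at most 5.88 FPKM in libraries 2 and 3. On RNAs this short that is very few counted units, so these calls, counted in the 68, lie near the detection floor. The small nucleolar RNAs F26D10.24 (1.78) and Y55F3BL.5 (-2.55) were also called and were not left out. Of the 12 largest remaining increases 5 were cyp-35 genes, namely cyp-35A2, cyp-35A3, cyp-35A4, cyp-35A5 and cyp-35C1, with log2 fold changes of 2.27 to 3.78 and adjusted p of 0.00215 to 0.00455 (limma). The others were both copies of clec-209 (4.02 and 2.37), irg-5 (3.59), clec-206 (3.59), fbxo-11.2 (2.93), irg-4 (2.59) and T16G1.6 (2.21). The clec-209 copies share sequence, so their split is uncertain. Called with smaller changes were ugt-8, ugt-16, ugt-22, ugt-67, cdr-1, irg-6, C32H11.4, stdh-2 and lbp-8, a lipid chaperone of the lysosome, whose log2 fold change was 1.75 (limma adjusted p = 0.0235). In the libraries not used for these calls, tryptophan 1 was above control 1 for 28 of the 34 higher genes, against 50.7% of all tested genes. It was below control 1 for only 4 of the 34 lower genes, so called genes of both directions mostly lay higher in tryptophan 1. The count therefore cannot show that the higher set holds in the libraries left out. The other 2 splits of these 4 libraries called 0 genes each. So few splits cannot set the 68 calls apart from chance, and in those splits a real effect would add to the spread. In simulated data of 2 against 2 libraries, calls among unchanged genes occurred in 4 of 20 draws.

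The 34 genes lower in libraries 2 and 3 held 7 nspd genes, a sperm-specific family of near-identical copies whose reads cannot be divided with certainty. nspd-7, nspd-2, nspd-5, nspd-3, nspd-6 and nspd-4 were among the 12 largest decreases that remained without genes annotated as piRNA or ncRNA, with log2 fold changes of -2.40 to -1.72. The rest of those 12 were clec-47 (-2.69), the small nucleolar RNA Y55F3BL.5 (-2.55), F16B4.4 (-2.31), cyp-13A4 (-2.17), W09G12.7 (-2.14) and nlp-25 (-1.91). Called with smaller changes were nlp-31 and nlp-33, which encode antimicrobial peptides, and cpr-4, a cathepsin B-like protease (-1.35, -1.46 and -1.42). Tryptophan 1 was below control 1 for 4 of these 34 genes, so the lower set ran the other way in the libraries left out. nspd-7 for example had 5.15 FPKM in control 1 and 194.4 FPKM in tryptophan 1.

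Metabolic and housekeeping lists passed camera in the lower direction, each with 0 members past the threshold over all genes or when adjusted over the list alone. They were lipid synthesis and desaturation (median log2 fold change -0.58, adjusted p = 1.3e-04), glycolysis, gluconeogenesis and the glyoxylate cycle (-0.53, 1.5e-04), the proteasome (-0.35, 8.8e-04), one-carbon and nucleotide metabolism (-0.52, 0.00153) and catabolism of other amino acids (-0.38, 0.00573), with adjusted p = 0.667 with an estimated correlation in each. Autophagy and lysosome genes (-0.41, 0.0165), ribosomal proteins (-0.21, 0.00389), histones (-0.27, 0.0224) and longevity signalling genes (-0.30, 0.0292) also passed, with adjusted p = 0.667, 0.746, 0.715 and 0.715 with an estimated correlation. Of these, ribosomal proteins and histones passed in the same direction in libraries 2 and 3 (medians -0.45 and -0.58, adjusted p = 3.8e-11 for both; adjusted p = 0.902 and 0.538 with an estimated correlation), longevity signalling genes passed in the other direction (0.25, adjusted p = 0.00471; adjusted p = 0.809 with an estimated correlation), and the others did not pass there. Means of 6 of these 9 lists were highest in control library 1 and lowest in tryptophan library 1, as for lipid synthesis (6.50 and 4.64, against 5.64 to 5.86 in the other 4). The ribosomal and histone means were instead highest in tryptophan library 1, at 11.45 and 3.22. Histone means were low in the other libraries too, at 2.06 to 2.95. The sum of all FPKM values was 1013590, 733462 and 824915 in control libraries 1 to 3 and 1115616, 715748 and 608336 in tryptophan libraries 1 to 3. Ribosomal means ranked the libraries in the same order as this sum. Both lists still passed camera with rescaling to TPM (adjusted p = 0.00294 and 0.00277). Whether library composition moved these 2 lists was not tested. Without tryptophan library 1 the lists of lipid synthesis (adjusted p = 0.0613), autophagy (0.587), other amino acid catabolism (0.0747) and longevity signalling (0.659) did not pass. Without control library 1 autophagy (0.145), the proteasome (0.145), other amino acid catabolism (0.125), ribosomal proteins (0.0613) and longevity signalling (0.307) did not. Ribosomal proteins also did not pass without control library 3 (0.0868), tryptophan library 2 (0.0972) or tryptophan library 3 (0.358), nor histones without tryptophan library 2 (0.603) or 3 (0.50). With quantile normalization ribosomal proteins (0.603), other amino acid catabolism (0.224), autophagy (0.222) and longevity signalling (0.0841) did not pass. With a filter of 5 FPKM ribosomal proteins (0.0584), other amino acid catabolism (0.0509), autophagy (0.0697), histones (0.0852) and longevity signalling (0.122) did not, nor did histones without a filter (0.184). Named values were -0.87 (SE 0.32) for acdh-1, an acyl-CoA dehydrogenase, 1.13 (SE 0.39) for cbs-1, a cystathionine beta-synthase, -1.02 (SE 0.43) for the desaturase fat-5 and -0.89 (SE 0.38) for mel-32.

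Moulting genes (median 0.73, adjusted p = 0.0165) and class 2 targets of DAF-16 (0.74, 0.0169) passed in the higher direction, with adjusted p = 0.715 and 0.667 with an estimated correlation and 0 members past the threshold over all genes or when adjusted over the list alone. The moulting mean was 2.14 in control library 1 and 3.56 in tryptophan library 1, against 4.36 to 4.66 elsewhere. The DAF-16 class 2 mean was 4.26 in control library 1 and 6.26 in tryptophan library 1, against 5.23 to 5.51 elsewhere. Neither list passed camera in libraries 2 and 3 (adjusted p = 0.0532 and 0.470). The moulting list did not pass without control library 1 (0.333) or tryptophan library 2 or 3 (0.191 for both), nor the DAF-16 list without tryptophan library 1 (0.0562). Without a filter neither passed (0.0599 and 0.226). Marker lists of muscle (adjusted p = 0.325), neurons (0.907), neuropeptides (0.0546), intestine (0.996), glia, coelomocytes and pharynx (0.0956), early embryo (0.0626) and late embryo (0.128) did not pass, nor did lipid breakdown (0.358), nuclear genes of oxidative phosphorylation (0.0736) and the mitochondrial genome (0.709). In libraries 2 and 3 alone, neuropeptides passed camera in the lower direction (adjusted p = 7.7e-09), with 12 members past the threshold when adjusted over the list alone and 3 over all genes. Those called over all genes were nlp-25, nlp-31 and nlp-33, and nlp-31 and nlp-33 are also in the antimicrobial list. Nuclear genes of oxidative phosphorylation passed in the lower direction too (2.7e-05), and the tyrosine and phenylalanine list passed in the higher direction (0.0344). The neuropeptide, oxidative phosphorylation and tyrosine and phenylalanine lists had adjusted p = 0.809, 0.902 and 0.809 with an estimated correlation. Over the 18 alternatives, neuropeptides passed higher in 7 and lower in 3, oxidative phosphorylation in 6, C-type lectins in 4, and late embryo and the glia, coelomocyte and pharynx list in 3 each, and early embryo passed in 5 of 17. Of all lists 14 passed in libraries 2 and 3, 6 of them in the same direction as over all libraries and 4 in the opposite direction. Among lists that did not pass, the direction turned under quantile normalization for the endoplasmic reticulum response, intracellular pathogen, oxidative phosphorylation and muscle lists, under rescaling to TPM for the endoplasmic reticulum response and neuron lists, and under median rescaling for the intestine list. The median differed in sign from the test for amino acid transport, the endoplasmic reticulum response, neurons and intestine.

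In total limma called 0 genes higher and 0 lower with tryptophan over the 6 libraries, with 158 genes at an unadjusted p under 0.05 (111 higher and 47 lower), fewer than the 676 that chance alone would give on average. Each alternative chosen before the values were seen also called 0, and the count at an unadjusted p under 0.05 was 388 without tryptophan library 1 and 82 without tryptophan library 3. The share of these genes that were higher was 70% over the 6 libraries, 37% without tryptophan library 1 and 89% without tryptophan library 3. Groups did not overlap for 1122 genes, or 8.3%, where chance gives 10%. camera called 21 of 46 lists, 11 higher and 10 lower, and 49 of 116 gene classes, and with an estimated correlation 0 lists and 0 classes. Without control library 1, 17 classes passed. In simulated data of the same 6 libraries without any change, camera called a median of 15.5 lists and at most 19, so a list call at the preset correlation carries little weight here.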

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

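The comparison of libraries 2 and 3, the stage score and the array quality weights were chosen after the result was seen, the other alternatives before. With 6 libraries limma called 0 genes higher and 0 lower in every alternative chosen before, leaving out each library included (0 to 0), with 77 to 388 genes at an unadjusted p under 0.05. Libraries 2 and 3 alone gave 34 higher and 34 lower, with 1890 at an unadjusted p under 0.05. Array quality weights gave 1599 higher and 2319 lower, but the weights ran from 0.08 to 29 without settling and other splits gave 0 to 9347 genes, so these calls carry no weight. The stage score gave 0 genes. The 21 lists became 0 with an estimated correlation and 0 with fry, and 15 to 26 when a library was left out; 7 of the 21 passed in the same direction without each library. The 49 classes became 0 with an estimated correlation, 28 with a filter of 5 FPKM, 19 with the stage score, 26 with array quality weights, and 17 (without control 1) to 54 when a library was left out. The cause of these losses was not tested. Set tests were not run for robust eBayes. The 20 genes with the smallest p kept their sign in every alternative that tested them. That follows largely from their selection, since their groups did not overlap. Of the 10 tested genes named whatever their values, 4 kept their sign. Rescaling to TPM moved the median log2 fold change of all genes from -0.03 to 0.07. A block on the replicate number gave 0 genes and 21 lists, not all of them the same, since collagens did not pass camera (adjusted p = 0.0840). Libraries of the same number deviated from their group means with correlations across genes of -0.37, -0.30 and -0.34, so these correlations show no sign of pairing. Control 1 and tryptophan 1, at opposite ends of the first principal component, weigh heavily in these values. On the second component both lay on the same side, at 55.3 and 68.7, against -45.0 to -9.1 in the other 4 libraries. An effect shared by libraries of the same number is therefore not excluded. With 3 against 3 libraries the simulated changes of log2 2 were called in 6% of cases and those of log2 1 in 2%, so smaller changes were seldom detectable.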

Other observations

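The tests on swapped treatment, depth and stage were chosen only after the result was seen. The counts over other splits and the test of scaling were chosen before.

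Some gene classes passed camera in the higher direction both over the 6 libraries and in libraries 2 and 3. The ugt and cyp classes, described above as lists, were among them (adjusted p = 2.0e-05 and 0.00695 for ugt, and 1.5e-04 and 0.0418 for cyp). The cest class of carboxylesterase-like genes was another (median log2 fold change 0.41, adjusted p = 0.00190, and 0.17, 0.00648). The rest were nep, a class of neprilysin-like peptidases (0.48, 0.0166, and 0.28, 0.00846), and ptr, patched-related genes, some of which are also in the moulting list (0.41, 0.0423, and 0.28, 1.4e-04). The lido class passed in the lower direction in both (-0.86, 0.00941, and -0.35, 0.0224). So did the rpl class of ribosomal proteins (-0.21, 0.00941, and -0.39, 1.5e-06) and the his class of histones (-0.21, 0.0433, and -0.56, 7.2e-10). Several classes passed in opposite directions, among them the msp class of major sperm proteins, whose copies share reads (median 1.44, then -0.46). Others were npp (-0.74, then 0.15) and lin (-0.58, then 0.32). With an estimated correlation the camera adjusted p was 0.746 over the 6 libraries and 0.965 in libraries 2 and 3 for each class named here.

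With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. For genes the real split gave 0 and the highest of the other splits 0, and 10 of 10 splits gave as many. For lists it gave 21 and the highest other 20, and 1 of 10 gave as many. For gene classes it gave 49 and the highest other 57, and 6 of 10 gave as many.

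Control 1 and tryptophan 1 stood apart from the other 4 libraries, and the test of a swap of their treatment gave mixed values. Among the 34 genes higher with tryptophan in libraries 2 and 3, tryptophan 1 exceeded control 1 by a median log2 of 2.82 (SE 0.42), against a swap. The 34 lower genes go the other way, with tryptophan 1 below control 1 for 4 of them, as a swap would give. Called genes of both directions thus mostly lay higher in tryptophan 1, so this test does not decide. Lower depth is argued against for control 1, since yolk genes, which are abundant, lay a median log2 of 4.57 above the other controls there (lowest gene 3.44). That test did not cover tryptophan 1. Control 1 and tryptophan 1 had the lowest estimated depths, at 14.8 and 17.5 M against 20.0 to 25.1 M in the other 4. Animals of a different stage may be the cause: the yolk minus sperm score differed by 9.72 between the 2 libraries, against a range of 2.63 among the other 4. This is a hypothesis found and tested on the same data, and a difference between cultures or in the time of collection stays open.

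The higher xenobiotic response genes were weighed against a linear trend with stage. With the score in the model the group difference of the list mean was 1.40 (SE 0.20), against 1.62 (SE 0.32) as deposited, so such a trend is unlikely to be the whole cause. This list mean rests largely on the cyp-35 genes. Rescaling to the same median left a difference of 1.61, but this test does not decide on scaling of the libraries. The medians of tested genes already lay at 10.71 to 12.59 FPKM in controls and 10.78 to 12.78 FPKM with tryptophan, so it could hardly change the difference. After rescaling to TPM, which gives each library the same sum, 8 members still rose when adjusted over the list alone. A response to the tryptophan diet may explain the higher xenobiotic response genes, as a hypothesis. Whether tryptophan itself or the bacteria grown with it acted was not tested.

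In libraries 2 and 3 the yolk list passed camera in the higher direction with tryptophan and the sperm and collagen lists in the lower direction. With an estimated correlation none did (adjusted p = 0.809, 0.538 and 0.538). Over all genes 0 yolk, 7 sperm and 0 collagen genes were called in these directions. If the tryptophan animals were further in development, the lists should move as they do between tryptophan 1 and control 1, and the Spearman correlation over the 46 lists was 0.12 (Pearson 0.31), between the 0 and 0.5 that would have decided it. The difference between control 1 and tryptophan 1 also carries the diet with its sign reversed, as in the xenobiotic list (1.56 and 3.82), so a diet effect would lower this correlation whether or not stage differs. A stage difference and a diet effect cannot be told apart for these lists.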
